A study of Mus musculus with 130 samples.

How the data were processed

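RNA was measured in single cells sorted into plates of 384 wells, 1 library per plate, with the pooled material linearly amplified and a unique molecular identifier (UMI) on each molecule. The deposited files hold counts per gene and well for each library. They are whole numbers, sum to different totals per well, and lie far below the reads listed per well, so they were taken as UMI counts. Per the submitters' processing notes, reads were handled with bcl2fastq 2.15.0.4 and the genome build was mm9. The aligner, the gene annotation and the rule for collapsing UMIs are not given in the sources used here. Also used was the authors' table of each well's library, sequencing batch, number of sorted cells and total reads, for 128 of the 130 libraries. Files held 33924 genes and 92 spike-in RNAs, under gene symbols of the mm9 period.

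Groups and abbreviations follow the source label of each sample, which does not tie libraries to mice. Titles hold library numbers, and libraries with consecutive numbers were called a run, which gave 20 runs in 19 sequencing batches. Spike-in RNAs took 12.2% to 75.2% of the counts in libraries of runs 1 to 8 and at most 0.397% in later runs, and they were left out of library sizes and tests. Wells listed with 0 cells were left out, as were wells under 500 UMIs, which left 18767 of 49920 wells. The 7 libraries with fewer than 20 kept wells were left out. No doublet caller was run, since wells were sorted to hold 1 cell. In kept wells of the libraries used the median was 616 to 2022 UMIs, so a gene at a few copies per cell is often counted at 0 in a well, and single wells were used only for clustering.

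Libraries were compared in pairs within a group (605 pairs) by the correlation of log well totals and by a chi-square test over genes with at least 10 counts. The 5 pairs with a correlation of at least 0.95 were taken as a plate sequenced again, and the rounded mean of both count tables was used as 1 library. This threshold was chosen after the values were seen. The plan had counted each library, now given as an alternative.

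Kept wells of all libraries, both sequencings of the 5 plates included, were clustered with scanpy 1.11.5 (python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9). Counts were scaled per well to its total without haemoglobin and salivary genes and log transformed. From genes with more than 500 UMIs in all, 800 variable genes were taken with the run as batch key, leaving out ribosomal, mitochondrial, predicted, immunoglobulin, haemoglobin and salivary genes and a further list of gland, red cell and islet genes, chosen because their counts were seen to follow such RNA. Then 20 principal components, 20 nearest neighbours and the Leiden method at resolution 1 gave 13 clusters. A cluster of at least 100 wells took the name of the class with the most markers, at least 3, at 10 CPM or more and at least 1.5 times the mean of the other clusters, unless another class had more markers among its top 10 genes by fold. Clusters 0, 1, 4 and 8 were named NK-like, 2 and 7 ILC1-like, 10 T-like, and 11 and 12 myeloid-like, and clusters 3, 5, 6 and 9 stayed unnamed. Markers were fixed before the data were examined. The clustering settings and the naming rule were set after clusters and their shares per group had been looked at, over several versions, because haemoglobin and salivary RNA led the first clusters. Of cluster 4's top 10 genes, 5 were haemoglobin genes when these were counted, and under that ranking it would have stayed unnamed. Shares with this cluster unnamed are among the alternatives. The ILC1-like share is the number of ILC1-like wells over that of NK-like plus ILC1-like wells in a library. It was compared with a two-sided permutation test of library shares in scipy 1.17.1, exact unless a group had too many splits, where 100000 were drawn, with Benjamini-Hochberg adjustment over 12 comparisons.

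For tests of genes, counts were summed over the kept wells of each library, since wells are not replicates. edgeR 4.0.16 in R 4.3.3 was run with TMM scaling, filterByExpr, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The fits held all 11 wild-type groups, the PyMT groups with Spleen (3 groups), or the 4 B16 groups, each group having its own mean. Within a fit the groups share their estimate of spread because several are small. The 17 gene comparisons include 3 on NK-like wells alone, in libraries with at least 10 such wells. Levels are CPM scaled with the TMM factors. Ratios against a group with 1 to 3 counts carry a 95% counting interval, and a group with 0 counts was set at 3 counts over the group. The 15 lists of gene programmes and 14 lists of markers of other cells were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation.

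Named genes follow a rule fixed before the data were examined. Among genes with adjusted p under 0.05, a mean of at least 50 CPM in the higher group, and the same sign of difference from the reference mean in every run of the group compared, those with the largest log2 fold changes could be named, 6 per direction for tissues and 10 for PyMT and B16 comparisons. Mitochondrial, ribosomal, predicted and spike-in genes and markers of other cells were left out of this ranking. In addition 2 to 6 members of each list with the smallest adjusted p could be named, and Eomes, Tbx21, Itga1, Cxcr6, Gzma, Gzmb, Prf1, Ifng, Klrg1 and Itgam in every comparison. Levels of haemoglobin, salivary, islet hormone and Y-linked genes, of genes resting on single Spleen runs or libraries, and of genes in single PyMT_Spleen libraries are given outside this rule and were chosen after the values were seen.

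In simulated data without run effects, 200 genes per comparison were changed by a log2 fold of 1 or 2. At a log2 fold of 2 the test recovered 73.5% of the changed genes for Blood, 27.9% for LP and 50.6% to 70.8% for the other tissues, each among 8683 genes tested against Spleen. It recovered 40.7% for PyMT_Tumor against PyMT_Spleen among 5865 genes, and 100% for CpG in B16 tumours and 79.8% in B16 spleens among 2917. At a log2 fold of 1 it recovered 53.1% for CpG in B16 tumours and 3.1% to 25.7% in the others, so most such changes were missed. At most 10% of calls were false in each, leaving false calls due to runs untested.

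Alternatives fixed before the data were examined were a minimum of 1000 UMIs per well, median-of-ratios scaling, no filter on low counts, DESeq2 1.42.0, only the groups compared in the fit, libraries summed or pooled by run, NK-like wells only, the run as a term for B16, each run or library left out in turn, LPL counted with LP, LN counted with Lymph_node, wells thinned to 500 UMIs before clustering, and wells assigned by the difference of marker scores, where 2067 wells lay within 0.05 of the boundary. Chosen after seeing the data were the run as a term for tissues and PyMT, alone or in a joint fit, fits within runs 6 and 11, fits without haemoglobin and salivary genes, libraries with at least 4 kept wells for PyMT, cluster 4 unnamed, and both sequencings of a plate counted. Figures were drawn with matplotlib 3.10.9.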

Results

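Natural killer (NK) cells and group 1 innate lymphoid cells (ILC1) are related lymphocytes that kill target cells or secrete interferon-gamma. Cells positive for NK1.1 and NCR1 and negative for CD3, CD19 and CD5 were sorted singly from C57BL/6 mice into plates of 384 wells. Transcripts were counted as UMIs, each standing for a captured RNA molecule. The 130 libraries, each from a plate, fell into 17 groups by tissue and treatment. Wild-type tissues gave Spleen (14 libraries), Blood (26), Lymph_node (7), Liver (7), Uterus (7), and the groups labelled VAT (9), SG (7), IEL (11), LP (4), LPL (2) and LN (1). Tumour-bearing mice gave PyMT_Tumor (9), PyMT_Spleen (6), B16_Tumor_CpG (6), B16_Tumor_cntrl (6), B16_Spleen_CpG (4) and B16_Spleen_cntrl (4). PyMT names a viral oncogene used in models of mammary tumours, B16 a mouse melanoma line, and CpG an unmethylated DNA motif that activates innate immune cells. The labels do not say what the shorter tissue names stand for or which mouse gave which plate, so p-values here measure only the spread between these libraries, which may be technical. Wells with at least 500 UMIs were kept, and libraries with fewer than 20 kept wells (PyMT_Spleen replicates 3 to 6, Blood replicates 20, 22 and 23) were left out. The libraries used held 17996 to 769867 UMIs in 23 to 329 kept wells, 22681124 UMIs in 18048 wells in all.

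Of 605 pairs of libraries within a group, 5 shared their pattern of UMIs over the wells of the plate, with correlations of log well totals from 0.963 to 0.995 against at most 0.842 for any other pair. In the 3 Blood pairs the gene counts differed by less than the sampling noise. In the 2 Spleen pairs the chi-square over its degrees of freedom was 1.04 and 1.10, against at least 1.75 in all other pairs. Each of the 5 pairs was counted as 1 library, which left 118, with n = 12 for Spleen and n = 20 for Blood. Libraries with consecutive numbers in their titles formed 20 runs, and only run 4 (1 Liver library) and run 11 (5 Uterus libraries) held Spleen together with another tissue. The run was therefore also fitted as a term where chains of shared runs allowed it, and the log2 difference then fell under 0.5 of its size for 4 of 10 named genes in Blood, 1 of 16 in Liver, 8 of 20 in VAT, 3 of 21 in SG, 0 of 16 in Uterus, 9 of 24 in IEL and 2 of 6 in PyMT_Spleen. For Lymph_node and LP against Spleen, and B16_Tumor_cntrl against B16_Spleen_cntrl run and group cannot be told apart. Several genes lower in many tissues rested on single Spleen runs or libraries. P2ry12 averaged 610 CPM (counts per 1000000) in the 2 Spleen libraries of run 2 and 0 in the 8 of runs 9 and 11, P2ry13 was at 1329 and 5.36 in the 2 libraries of run 4 and 0 in the same 8, and AC154124.1 196 in run 9 and at most 7.83 in the means of the other runs. These genes had some of the largest log2 differences against Spleen and are not described further.

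Wells were clustered on expression and clusters were named from fixed markers, giving NK-like wells (Eomes, the Ly49 genes Klra4 and Klra8) and ILC1-like wells (Cxcr6, Itga1, Tmem176b, and in cluster 7 Il7r). The ILC1-like share of these wells in each library was 71.2% ± 5.71 (SD, n = 11) in IEL and 74.4% ± 4.97 (SD, n = 4) in LP, against 10.0% ± 3.04 (SD, n = 12) in Spleen. It was 39.8% ± 28.9 (SD, n = 7) in Liver, 34.0% ± 17.99 (SD, n = 9) in VAT and 17.9% ± 3.25 (SD, n = 7) in Lymph_node, each above Spleen (permutation test of library shares, two-sided, adjusted p = 7.94e-05 for IEL, VAT and Lymph_node, 0.000774 for Liver and 0.00132 for LP). Every library of IEL, LP, VAT and Lymph_node and 6 of 7 of Liver lay above the Spleen mean. The raw p of 1.00e-05 for IEL and of 0.000549 for LP is the smallest that the permutations can give. Shares in Blood (8.15% ± 4.25 (SD, n = 20)), SG (11.4% ± 4.07 (SD, n = 7)) and Uterus (11.2% ± 9.67 (SD, n = 7)) did not pass the threshold against Spleen in this test (adjusted p = 0.300, 0.512 and 0.772, permutation test). Among tumour-bearing mice, PyMT_Tumor had 22.6% ± 12.3 (SD, n = 9) and PyMT_Spleen 11.9% ± 0.387 (SD, n = 2) (exact permutation test, adjusted p = 0.339). B16_Tumor_cntrl had 20.4% ± 3.62 (SD, n = 6) against 8.58% ± 6.60 (SD, n = 4) in B16_Spleen_cntrl (exact permutation test, adjusted p = 0.0191, above the spleen mean in 6 of 6). B16_Spleen_CpG had 21.2% ± 3.88 (SD, n = 4), above B16_Spleen_cntrl (exact permutation adjusted p = 0.0490, 4 of 4), and B16_Tumor_CpG 19.6% ± 7.60 (SD, n = 6), not past the threshold against its control (adjusted p = 0.831).

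**Figure D1:**
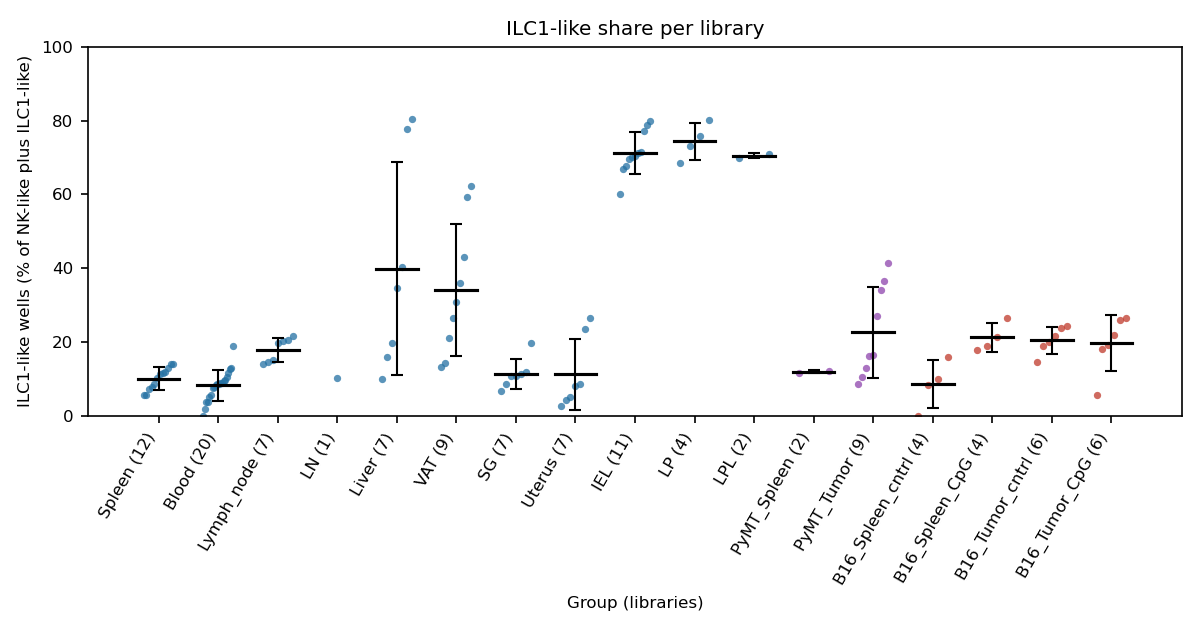
ILC1-like share of NK-like plus ILC1-like wells (vertical axis, percent) in each library (points) of each group (horizontal axis), with the group mean and SD as a line and bar where a group has more than 1 library. IEL, LP and LPL libraries lie above 60%, and Liver libraries run from 9.86% to 80.6%.

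Within run 4 the Liver library had 15.8% ILC1-like wells and the 2 Spleen libraries a mean of 8.63%. Within run 11 the mean was 5.66% in 5 Uterus and 8.37% in 5 Spleen libraries, while the 2 Uterus libraries of run 8 had 24.97%. Uterus differed from Spleen by -4.34 percentage points without run 8 (adjusted p = 0.0247) and by 14.97 without run 11 (adjusted p = 0.0188). With libraries pooled by run IEL and VAT passed (adjusted p = 0.0490 each), and Lymph_node (0.114), Liver (0.114) and LP (0.3) did not, their 2, 2 and 1 runs allowing no raw p under 0.0667, 0.0667 and 0.2. VAT ranged from 21.1% in run 10 to 60.8% in run 7. PyMT_Tumor had 34.7% in run 6, against 11.9% for PyMT_Spleen in that run, and 12.9% in run 14. Among B16 libraries the shares of B16_Spleen_CpG and B16_Spleen_cntrl were 20.2% and 8% in run 14 and 22.2% and 9.17% in run 17, and those of B16_Tumor_CpG and B16_Tumor_cntrl 22.5% and 18.9% in run 15 and 16.6% and 21.9% in run 16. Only the higher shares of IEL, LP and Liver passed under every other way tried of assigning wells to the 2 classes. SG minus Spleen passed in both directions: 21.2 percentage points (adjusted p = 5.95e-05) with wells thinned to 500 UMIs, 14.4 (5.95e-05) by marker score, -5.98 (0.0302) with at least 1000 UMIs and -14.0 (0.00163) with cluster 4 unnamed, and Uterus likewise: 9.51 (0.0238), not past the threshold by marker score, -8.82 (0.000905) and -12.9 (0.0163). Blood passed by marker score (-1.27, adjusted p = 0.0138), and PyMT_Tumor thinned (26.3) and by marker score (10.4, 0.0312 each). Among wells of at least 1000 UMIs the differences for Lymph_node (-1.85), CpG in B16 spleen and B16 tumour against spleen changed sign, and VAT differed by 1.96. B16_Tumor_CpG then differed from its control by -13.1 (adjusted p = 0.00433), and with wells thinned to 500 UMIs by -10.2 (0.00866).

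From here counts were summed over the kept wells of each library. Levels are mean CPM ± SD over libraries, differences are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and rose, fell, higher and lower are used of genes past an adjusted p of 0.05. Folds against a group with 0 counts are lower bounds, set against a floor of 3 counts over the group, and intervals on ratios cover counting error only. Each gene list was tested as a set with camera, and the p with a correlation estimated from the data stands beside a list wherever it missed the threshold. The Ly49 (Klra), haemoglobin and granzyme genes have near-identical relatives, and how their shared reads were counted is not given in the sources used here, so single members are uncertain. Among all 17 comparisons no member of the lists for ILC2, ILC3 and melanoma cells passed the filter on low counts.

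Blood was set against Spleen to compare circulating with splenic cells. Gzmb, a granzyme of killer cells, was higher in Blood at 1320 ± 603 CPM (SD, n = 20) against 714 ± 264 CPM (SD, n = 12), a log2 difference of 0.88 ± 0.21 (adjusted p = 0.00835, above the Spleen mean in 19 of 20 libraries). The chemokine gene Ccl4 rose by 1.93 ± 0.37 and Nme1 by 1.07 ± 0.22. Tcf7, which encodes the transcription factor TCF-1 of early NK cells, fell from 294 ± 114 to 105 ± 60.9 CPM (-1.34 ± 0.22, adjusted p = 1.09e-05), and the cytokine receptor gene Il7r (-1.98 ± 0.42) was also lower. Itga1, the integrin chain CD49a, was counted 27 times in Blood and 3 in Spleen, a ratio of 10.7 (counting interval 3.29 to 55.0). The erythroid and platelet list rose, with 5 higher and 0 lower of 7 measured (6 and 0 adjusted over the list alone, camera adjusted p = 5.10e-13). Its haemoglobin gene Hba-a2 reached 21800 ± 21760 CPM against 49.7 ± 158, above the Spleen mean in 11 of 20 libraries, and Bpgm, an enzyme of red cells, rose by 4.65 ± 0.66. Haemoglobin came from Blood runs 3 and 18 (119100 to 421100 per 1000000 UMIs). Runs 6, 19 and 20 held at most 122.1 and Spleen 3403. MHC class I processing genes such as B2m (-0.47 ± 0.12) and Psmb9 (-0.80 ± 0.22, 0.11 with the run as a term) were lower. On the list 0 of 17 measured genes were higher and 2 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.000607, 0.157 with an estimated correlation). The lineage transcription factors were lower as a set. Measured members numbered 19, with 0 higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.00445). In all 369 of 10032 genes passed (134 higher and 235 lower). With the run as a term 6 passed, with only these groups in the fit 60, and with libraries summed by run 0 (edgeR, 898 of 11615 at an unadjusted p under 0.05, and 269 with DESeq2 on the unsummed libraries). With the run term the log2 difference was -1.11 for Tcf7 (adjusted p = 0.695) and 0.71 for Gzmb (adjusted p = 0.817).

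Lymph_node cells differed from Spleen cells in genes of NK maturation. Cma1, a protease gene of mature mouse NK cells, fell from 456 ± 245 to 115 ± 46.1 CPM (SD, n = 12 and 7), a log2 difference of -2.00 ± 0.47 (adjusted p = 0.00974, below the Spleen mean in 7 of 7), and Spn, the CD43 gene, fell (-0.90 ± 0.24). The chemokine gene Xcl1 rose from 311 ± 169 to 658 ± 147 CPM (1.09 ± 0.30), and Fbxl18 by 2.68 ± 0.58. Odc1 averaged 54.1 ± 19.7 CPM against 10.8 ± 10.2 (adjusted p = 0.0118). The granzyme gene Gzmc averaged 174 ± 403 CPM against 8.26 ± 22.6 (3.93 ± 0.83, above the Spleen mean in 5 of 7), with 1087 CPM in replicate 1 and at most 79.9 in the others. Glycam1, a product of the specialised venules of lymph nodes, was at least 81.4-fold higher, in 3 of 7 libraries. The NK maturation and circulation list was lower. Of its 15 measured genes 0 were higher and 2 lower (0 and 4 adjusted over the list alone, camera adjusted p = 3.90e-06, 0.157 with an estimated correlation). The immature NK list was higher. Of its 12 measured genes 1 were higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 9.63e-06). Immediate-early and dissociation genes such as Hspa8 (0.80 ± 0.22) were higher. Measured members numbered 23, with 2 higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 0.000536, 0.275 with an estimated correlation). In all 125 of 10032 genes passed (119 higher and 6 lower), and 84 (66 and 18) with median-of-ratios scaling, which moved the median log2 difference of all genes from 0.01 to -0.16. No gene passed in edgeR with libraries summed by run (0 of 11615 genes, 401 at an unadjusted p under 0.05, and 141 with DESeq2 on the unsummed libraries). The 401 are fewer than chance alone would give among the genes tested.

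Liver libraries carried the markers of ILC1. Cxcr6, a chemokine receptor, rose from 24.5 ± 36.0 to 406 ± 297 CPM (SD, n = 12 and 7), a log2 difference of 4.35 ± 0.58 (adjusted p = 5.13e-08, above the Spleen mean in 7 of 7). Itga1 had a ratio of 82.2 (counting interval 27.8 to 402), and Cd200r2, a receptor related to the CD200 receptor, was at least 76.9-fold higher. Gzmb (1.94 ± 0.26), Tnfsf10, which encodes the death ligand TRAIL (2.42 ± 0.47), Cish (3.38 ± 0.46), Xcl1 (1.59 ± 0.29) and Cd3g (4.01 ± 0.58) rose in 7 of 7 libraries. Klf2, a transcription factor that drives recirculation, fell (-1.12 ± 0.33), and so did the integrin gene Itga4 (-1.16 ± 0.29), Tcf7 (-1.36 ± 0.28) and the Ly49 receptor gene Klra8 (-1.04 ± 0.28). The ILC1 and tissue residency list rose. Of its 21 measured genes 8 were higher and 0 lower (14 and 1 adjusted over the list alone, camera adjusted p = 4.66e-09). The Ly49 list was lower, with 1 higher and 1 lower of 9 measured (1 and 4 adjusted over the list alone, camera adjusted p = 5.49e-08), Klra5 being the higher member (2.18 ± 0.63). Checkpoint and costimulatory receptor genes, among them Klrc1 (0.99 ± 0.27, and -0.10 with only the Liver library outside run 10) and Tnfrsf18 (1.03 ± 0.29), were higher. Measured members numbered 13, with 3 higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.000800). The hepatocyte list was higher too, with 1 higher and 0 lower of 3 measured (3 and 0 adjusted over the list alone, camera adjusted p = 0.000509), and Alb averaged 68.6 ± 63.9 CPM against 0.571 ± 1.98. The myeloid list was lower. Of its 10 measured genes 0 were higher and 4 lower (0 and 7 adjusted over the list alone, camera adjusted p = 0.000292, 0.108 with an estimated correlation). In all 228 of 10032 genes passed (144 higher and 84 lower), and with median-of-ratios scaling 243 (128 and 115). A run term left 3 genes past the threshold, and the log2 difference was 3.11 for Cxcr6 (adjusted p = 0.179), 1.23 for Gzmb (adjusted p = 0.188) and -0.11 for Klf2 (adjusted p = 1.00). With libraries summed by run 6 passed, with only these groups fitted 83.

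In VAT, immediate-early and residency genes were higher than in Spleen. Dusp1, a phosphatase induced by stress, rose from 6.53 ± 14.3 to 254 ± 171 CPM (SD, n = 12 and 9), a log2 difference of 5.36 ± 0.62 (adjusted p = 1.84e-10, 9 of 9), and the transcription factor genes Fos and Egr1 rose by 4.01 ± 0.59 and 4.14 ± 0.77. The immediate-early and dissociation list rose. Of its 23 measured genes 13 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 9.15e-18). Residency genes rose as well, with 10 higher and 1 lower of 21 measured (14 and 2 adjusted over the list alone, camera adjusted p = 5.95e-06), among them Rgs1 (3.47 ± 0.47), Rgs2 (3.03 ± 0.48), the activation marker Cd69 (2.51 ± 0.47) and Tmem176a (2.49 ± 0.60), while Kit, a growth factor receptor on the same list, fell (-3.31 ± 0.58). Cytokine and chemokine genes went both ways, with 4 higher and 2 lower of 15 measured (5 and 3 adjusted over the list alone, camera adjusted p = 0.0681, 0.228 with an estimated correlation), Ifng (2.25 ± 0.40), Ccl4 (2.89 ± 0.41) and Ccl3 (1.82 ± 0.37) being higher and Ccl5 (-0.63 ± 0.17) lower. Thy1, a surface glycoprotein, rose by 1.97 ± 0.29, and the maturation genes S1pr5, a receptor for exit into blood (-1.72 ± 0.47), Itgam (-1.39 ± 0.38) and Itga4 (-1.25 ± 0.27) fell. Gzma fell from 12710 ± 2527 to 8061 ± 2742 CPM (-0.66 ± 0.20). A run term put the log2 differences of Gzma (0.72), S1pr5 (0.76) and Ccl5 (0.05) above 0, not past the threshold. Stroma and endothelium genes moved with this group, with 6 higher and 0 lower of 7 measured (6 and 0 adjusted over the list alone, camera adjusted p = 2.04e-05), and so did the adipocyte genes Fabp4, at 1317 ± 2625 CPM against 3.07 ± 7.76, and Cfd, 2 of 2 measured being higher and 2 adjusted over the list alone. The largest rises outside the lists were Ptrf and Cav1, genes of the caveolae of fat and endothelial cells, at least 72.9- and 54.0-fold higher. In all 450 of 10032 genes passed (360 higher and 90 lower). With the run as a term no gene passed in edgeR (0 genes, 842 at an unadjusted p under 0.05, and 213 with DESeq2 without that term), and the log2 difference was 4.41 for Dusp1 (adjusted p = 0.141) and 1.16 for Rgs1 (adjusted p = 0.605). With only these groups fitted 111 passed, and with libraries summed by run 70.

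SG libraries had low levels of maturation genes. Klf2 fell from 606 ± 171 to 35.5 ± 17.4 CPM (SD, n = 12 and 7), a log2 difference of -4.05 ± 0.40 (adjusted p = 6.21e-14, 7 of 7 below the Spleen mean), and S1pr5 (-5.65 ± 0.69), Cma1 (-6.75 ± 0.69) and Klrg1, an inhibitory receptor (-4.46 ± 0.51), fell as well. The NK maturation and circulation list fell. Of its 15 measured genes 0 were higher and 14 lower (0 and 15 adjusted over the list alone, camera adjusted p = 1.85e-36). Gzma fell from 12710 ± 2527 to 772 ± 242 CPM (-4.04 ± 0.26), and the perforin gene Prf1 (-1.26 ± 0.30), the T-bet gene Tbx21 (-1.07 ± 0.29) and Ccl5 (-2.54 ± 0.20) fell too. Gzmc rose to 940 ± 418 CPM from 8.26 ± 22.6 (6.19 ± 0.81), Xcl1 by 3.29 ± 0.30, Tnfsf10 by 2.73 ± 0.47 and Rgs1 by 3.32 ± 0.49. The TGF-beta response list rose, with 5 higher and 0 lower of 11 measured (5 and 0 adjusted over the list alone, camera adjusted p = 0.000116): Itgae, the CD103 integrin chain, averaged 171 ± 52.5 CPM against 2.04 ± 5.30 (5.68 ± 0.66), Pmepa1 rose by 2.94 ± 0.62 and Itga1 had a ratio of 59.3 (counting interval 20.0 to 290). Il7r (-3.88 ± 0.61) and Kit (-2.78 ± 0.56), both on the residency list, fell. Immediate-early genes such as Fos (3.94 ± 0.61) and Dusp1 (4.25 ± 0.66) were higher. Measured members numbered 23, with 14 higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 1.90e-05, 0.0994 with an estimated correlation). Gland transcripts took 265500 ± 225800 per 1000000 UMIs (SD, n = 7) for 6 salivary secretory genes, Abpa alone 179100 ± 200000 CPM against 0. The salivary acinar list was higher, with 5 higher and 0 lower of 5 measured (5 and 0 adjusted over the list alone, camera adjusted p = 6.00e-05, 0.0565 with an estimated correlation), and the epithelium list likewise, with 3 higher and 0 lower of 4 measured (3 and 0 adjusted over the list alone, camera adjusted p = 0.00742, 0.0994 with an estimated correlation). Lef1, on the T cell list, was lower (-1.69 ± 0.55). On the list 0 of 5 measured genes were higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.0139, 0.0565 with an estimated correlation). In all 1116 of 10032 genes passed (816 higher and 300 lower), and 1270 without haemoglobin and salivary genes. Fitted with a run term 52 passed, 7 of the 21 genes named here among them, such as Klf2 (-3.12) and Gzma (-2.70), while Rgs1 (0.05, adjusted p = 1.00), S1pr5 (-2.25, 0.513), Klrg1 (-2.59, 0.106), Gzmc (4.94, 0.296), Itgae (8.36, 0.0639), Dusp1, Prf1 and Tbx21 were among those that did not pass. With only these groups fitted 633 passed, and with libraries summed by run 288.

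Uterus libraries combined lower maturation genes with higher proliferation genes. Klf2 fell from 606 ± 171 to 68.2 ± 40.5 CPM (SD, n = 12 and 7), a log2 difference of -3.20 ± 0.39 (adjusted p = 1.03e-09, 7 of 7 below the Spleen mean), as did Cma1 (-3.23 ± 0.52), Gzma (-1.99 ± 0.23), Ccl5 (-2.28 ± 0.20) and the transcription factor gene Klf3 (-4.13 ± 0.67). The maturation list fell. Of its 15 measured genes 0 were higher and 10 lower (0 and 13 adjusted over the list alone, camera adjusted p = 3.28e-23). Cdh1, the E-cadherin gene, was at least 68.0-fold higher, at 111 ± 24.8 CPM in 7 of 7 libraries, and Itga1 had a ratio of 91.9 (counting interval 31.0 to 449). Gzmc rose by 5.43 ± 0.81, Spp1, which encodes osteopontin, by 4.77 ± 0.78, Thy1 by 2.29 ± 0.30, Xcl1 by 2.27 ± 0.29 and Pmepa1 by 3.81 ± 0.62. The proliferation list rose, with 10 higher and 0 lower of 24 measured (17 and 1 adjusted over the list alone, camera adjusted p = 1.88e-11), as in Mki67, the Ki-67 gene (3.13 ± 0.71), Birc5 (3.90 ± 0.87) and Mcm5 (1.74 ± 0.45). The TGF-beta response list was higher, with 4 higher and 0 lower of 11 measured (5 and 1 adjusted over the list alone, camera adjusted p = 0.00248), and so was glycolysis and hypoxia, with 5 higher and 0 lower of 20 measured (5 and 0 adjusted over the list alone, camera adjusted p = 0.00649). Antigen presenting cell genes such as H2-Eb1, counted 2 times in Uterus and 100 in Spleen, were lower. On the list 0 of 5 measured genes were higher and 4 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.00258, 0.247 with an estimated correlation). In all 467 of 10032 genes passed (316 higher and 151 lower), and 460 (221 and 239) with median-of-ratios scaling. Within run 11, which held 5 libraries of each group, 116 of 1652 genes passed (43 higher and 73 lower). With the run as a term 70 passed, 10 of the 16 genes named here among them, such as Klf2 (-2.79) and Cdh1 (6.57). The proliferation genes Mki67 (3.64, adjusted p = 0.131), Birc5 (2.93, 0.241) and Mcm5 (1.84, 0.153) did not pass then, nor did Gzmc, Spp1 and H2-Eb1. With libraries summed by run 46 passed.

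IEL libraries carried the tissue residency programme. Cxcr6 rose from 24.5 ± 36.0 to 560 ± 238 CPM (SD, n = 12 and 11), a log2 difference of 4.81 ± 0.55 (adjusted p = 2.92e-11, 11 of 11), Rgs1 by 5.16 ± 0.47, Cd160 by 2.40 ± 0.26, Hic1 by 4.26 ± 0.56 and Itgae by 4.75 ± 0.64. The ILC1 and tissue residency list rose. Of its 21 measured genes 19 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 9.99e-30). Ccr9, a gut homing receptor, was at least 152-fold higher, at 232 ± 82.0 CPM, and Cdh1 at least 66.7-fold. Itga1 had a ratio of 112 (counting interval 38.1 to 544) and P2rx7 of 148 (40.9 to 1228). The T-box factor gene Eomes fell from 468 ± 118 to 138 ± 53.0 CPM (-1.77 ± 0.31), as did Gzma (-1.02 ± 0.19), Prf1 (-1.26 ± 0.26), Klrg1 (-2.72 ± 0.37), Itgam (-2.74 ± 0.37) and Klf2 (-3.12 ± 0.31). The log2 differences of Eomes (0.23) and Gzma (0.48) lay above 0 with the run as a term and did not pass the threshold. The NK maturation and circulation list fell, with 0 higher and 13 lower of 15 measured (0 and 14 adjusted over the list alone, camera adjusted p = 2.71e-38), and so did the Ly49 receptors, with 0 higher and 7 lower of 9 measured (0 and 7 adjusted over the list alone, camera adjusted p = 1.48e-16), for example Klra9 (-1.80 ± 0.21) and Klra8 (-1.94 ± 0.25). Checkpoint and costimulatory receptor genes rose, with 6 higher and 0 lower of 13 measured (6 and 1 adjusted over the list alone, camera adjusted p = 2.35e-06), as did cytokine and chemokine genes, with 8 higher and 1 lower of 15 measured (10 and 1 adjusted over the list alone, camera adjusted p = 3.13e-05): Lag3 was higher by 4.21 ± 0.61, Cd226 by 2.37 ± 0.37, Xcl1 by 2.13 ± 0.27 and Ifng by 1.38 ± 0.39, while Ccl5 was lower (-1.11 ± 0.16). The interferon-gamma-induced GTPases were higher as a set. Measured members numbered 20, with 2 higher and 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 0.000959). Immediate-early and dissociation genes rose, with 16 higher and 0 lower of 23 measured (17 and 0 adjusted over the list alone, camera adjusted p = 9.93e-17), Fos averaging 676 ± 294 CPM against 14.3 ± 24.0. Epithelium genes moved with this group, Epcam at 54.1 ± 77.2 CPM against 1.10 ± 3.82, with 3 higher and 0 lower of 4 measured (3 and 0 adjusted over the list alone, camera adjusted p = 0.00489, 0.0542 with an estimated correlation), and salivary RNA reached 47380 per 1000000 UMIs in the IEL library that held most. In all 790 of 10032 genes passed (470 higher and 320 lower). Under a run term 40 passed, and the log2 difference was 2.62 for Cxcr6 (adjusted p = 0.273), -1.97 for Klf2 (adjusted p = 0.170) and 1.84 for Rgs1 (adjusted p = 0.170). With libraries summed by run 201 passed.

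LP libraries, all of run 16, were also led by residency and immediate-early genes. Rgs1 rose from 37.7 ± 31.9 to 2909 ± 90.4 CPM (SD, n = 12 and 4), a log2 difference of 6.09 ± 0.53 (adjusted p = 2.64e-16, 4 of 4), Tmem176b by 4.36 ± 0.57, Cxcr6 by 4.33 ± 0.64 and Cd69 by 3.72 ± 0.54. The ILC1 and tissue residency list rose. Of its 21 measured genes 15 were higher and 0 lower (18 and 0 adjusted over the list alone, camera adjusted p = 3.38e-32). Ccr9 was at least 208-fold and Cdh1 at least 50.2-fold higher than in Spleen. Klf2 (-3.35 ± 0.51), Gzma (-1.87 ± 0.29), Prf1 (-2.42 ± 0.44), Eomes (-1.88 ± 0.48) and Itga4 (-2.85 ± 0.42) fell. The maturation list fell, with 0 higher and 10 lower of 15 measured (0 and 13 adjusted over the list alone, camera adjusted p = 8.11e-22), and the Ly49 receptors, with 0 higher and 5 lower of 9 measured (0 and 7 adjusted over the list alone, camera adjusted p = 1.03e-10), among them Klra4 (-2.29 ± 0.42). Among lineage transcription factors Bhlhe40 (2.28 ± 0.41), Klf6 (1.92 ± 0.37) and Ikzf2, which encodes Helios (2.41 ± 0.61), rose, and Rorc, the ROR-gamma-t gene of group 3 cells, was counted in Spleen 0 times and averaged 28.8 ± 29.4 CPM in LP. Measured members numbered 19, with 4 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0247, 0.0807 with an estimated correlation). Checkpoint and costimulatory receptor genes rose, with 6 higher and 0 lower of 13 measured (6 and 0 adjusted over the list alone, camera adjusted p = 1.68e-07), as in Cd96 (1.76 ± 0.33) and Lag3 (3.13 ± 0.75). Immediate-early and dissociation genes rose, with 14 higher and 0 lower of 23 measured (16 and 0 adjusted over the list alone, camera adjusted p = 1.11e-21): Junb averaged 1571 ± 253 CPM against 90.4 ± 56.4, and Dusp1 664 ± 63.6 against 6.53 ± 14.3. In all 360 of 10032 genes passed (213 higher and 147 lower). Without LP replicate 1 the number was 234, with LPL libraries added 613, and with libraries summed by run, where LP is 1 sample assumed to vary like the other groups, 43.

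**Figure D2:**
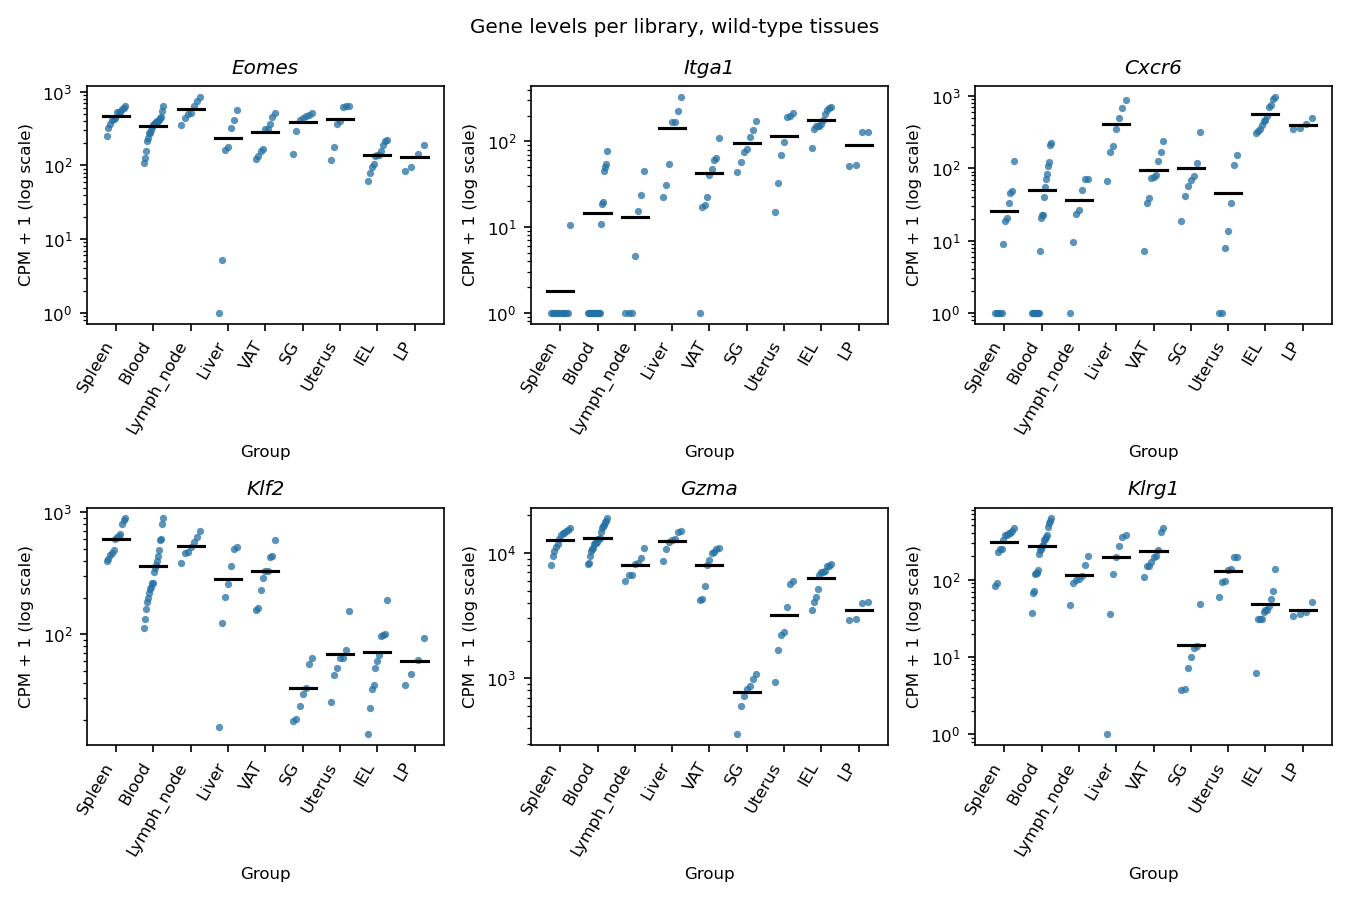
Levels of Eomes, Itga1, Cxcr6, Klf2, Gzma and Klrg1 (vertical axes, CPM plus 1 on a log scale) in each library (points) of Spleen and the tissues compared with it (horizontal axes), with the group mean as a line. IEL and LP libraries lie above every Spleen library for Itga1 and Cxcr6, below every Spleen library for Eomes and Klf2, and below most of them for Gzma and Klrg1.

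In PyMT_Tumor, set against PyMT_Spleen to compare tumour with spleen of tumour-bearing mice, the maturation genes fell. S1pr5 fell from 239 ± 4.60 to 4.83 ± 6.25 CPM (SD, n = 2 and 9), a log2 difference of -5.12 ± 0.49 (adjusted p = 1.32e-09, 9 of 9 below the spleen mean), as did Cma1 (-5.87 ± 0.61), Klf2 (-2.48 ± 0.38), Itga4 (-2.06 ± 0.27) and Klrg1 (-2.15 ± 0.52). The NK maturation and circulation list fell. Of its 15 measured genes 0 were higher and 6 lower (1 and 10 adjusted over the list alone, camera adjusted p = 5.17e-22). Ccl5 fell from 17300 ± 652 to 1460 ± 517 CPM (-3.55 ± 0.23), and lower levels were also found for Gzma (-2.28 ± 0.23), Il7r (-2.46 ± 0.55) and Cd160 (-1.77 ± 0.41). Gzmc rose from 223 ± 198 to 3296 ± 1872 CPM (3.92 ± 0.74), Spp1 by 5.12 ± 1.24, Rgs1 by 4.04 ± 0.94, the cytokine gene Tgfb1 by 3.03 ± 0.76 and Thy1 by 1.79 ± 0.39. Pmepa1, a gene induced by TGF-beta, was at least 15.1-fold higher. Glycolysis and hypoxia genes were higher as a set. On the list 0 of 16 measured genes were higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.000533). Genes of the erythroid and platelet list, mostly haemoglobin, were lower in the tumour. Measured members numbered 4, with 0 higher and 3 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.000657, 0.169 with an estimated correlation). In all 51 of 6499 genes passed (18 higher and 33 lower). Transcripts of 4 Y-linked genes took 88.6 to 137.6 per 1000000 UMIs in the 4 tumour libraries of run 6, 0 in the 5 of run 14, 19.9 to 34.3 in PyMT_Spleen and at most 14.04 in Spleen. Within run 6, which held both groups, 183 passed, and with the run as a term 139 (85 higher and 54 lower), 15 of the 15 genes named here among them. With only these 2 groups fitted 152 passed, without PyMT_Spleen replicate 1 the number was 13 and without replicate 2 27, with libraries of 4 or more kept wells included 132, and with libraries summed by run 9 (0 higher and 9 lower). Of kept wells, myeloid-like clusters 11 and 12 held 6.56% and 6.62% in PyMT_Tumor and 0.99% and 17.5% in PyMT_Spleen. Among NK-like wells alone Gzmc (1.51, adjusted p = 0.485), Spp1 (3.08, 0.388), Rgs1 (3.67, 0.0505), Tgfb1 (3.01, 0.101), Thy1 and Pmepa1 did not pass.

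Among NK-like wells alone, of which cluster 0 held the most in PyMT_Tumor and cluster 4 in PyMT_Spleen, 32 of 4128 genes passed (5 higher and 27 lower). S1pr5 (-4.52 ± 0.56), Cma1 (-5.07 ± 0.61), Ccl5 (-3.18 ± 0.26), Klf2 (-2.61 ± 0.42) and Gzma (-2.24 ± 0.24) fell, and so did Ly6c2, a surface antigen (-2.61 ± 0.46). Bcl2l11, which encodes the death regulator BIM, rose by 3.61 ± 0.82, Prdx6 by 2.98 ± 0.63 and Sh2d2a by 1.90 ± 0.43. The maturation list fell here too. Of its 14 measured genes 0 were higher and 6 lower (1 and 10 adjusted over the list alone, camera adjusted p = 1.14e-18). With the run as a term 66 passed, and without PyMT_Spleen replicate 1 or 2 the numbers were 9 and 11, and with libraries summed by run 4. PyMT_Spleen (n = 2) differed from wild-type Spleen (n = 12) in few genes: 9 of 6499 genes passed (9 higher and 0 lower). Gzmc rose from 8.72 ± 23.7 to 223 ± 198 CPM (3.96 ± 0.68), Anxa5 by 3.26 ± 0.51, Parp1 by 2.69 ± 0.52 and Cct5 by 1.41 ± 0.29, and Gzmd was at least 21.2-fold higher. These genes differed between the PyMT_Spleen libraries, replicates 1 and 2 holding Gzmc at 83.0 and 363 CPM, Anxa5 at 706 and 135, Parp1 at 96.9 and 327, and Pabpn1 at 2828 and 135 (Spleen mean 150 ± 87.2). Anxa5, Gzmd and Pabpn1 did not pass without replicate 1, and Gzmc, Parp1 and Cct5 did not without replicate 2. Without replicate 1 the number was 5 and without replicate 2 6, and with only these groups fitted 2. With the run as a term of a joint fit with the tissues 0 passed (edgeR, 838 at an unadjusted p under 0.05), and the log2 difference of Gzmc was 0.46.

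B16_Tumor_CpG (202953 to 374809 UMIs per library) was set against B16_Tumor_cntrl (67028 to 149901) for the response to CpG in the tumour. Killing, glycolysis and proliferation genes rose. Gzmb rose from 926 ± 274 to 4069 ± 1996 CPM (SD, n = 6 and 6), a log2 difference of 2.12 ± 0.26 (adjusted p = 1.88e-06, 6 of 6), Gzmc from 502 ± 280 to 4883 ± 3640 CPM (3.27 ± 0.49), Prf1 by 1.45 ± 0.23 and Gzma by 0.88 ± 0.14. The cytotoxic effector list rose. Of its 12 measured genes 5 were higher and 0 lower (6 and 1 adjusted over the list alone, camera adjusted p = 1.46e-05). Ly6a, the stem cell antigen Sca-1, rose by 2.59 ± 0.26, Klrg1 by 2.20 ± 0.32, Spp1 by 3.14 ± 0.43, the transferrin receptor gene Tfrc by 3.34 ± 0.61 and Tnfrsf9, the costimulatory receptor 4-1BB, by 1.13 ± 0.21. Glycolysis and hypoxia genes rose, with 7 higher and 0 lower of 15 measured (13 and 0 adjusted over the list alone, camera adjusted p = 2.00e-15), among them Pkm2 (1.37 ± 0.19), Pgk1 (1.23 ± 0.19), Ldha (1.11 ± 0.18) and Ero1l (2.58 ± 0.54). Proliferation genes rose, with 9 higher and 0 lower of 24 measured (16 and 0 adjusted over the list alone, camera adjusted p = 5.79e-14), as in Rrm2 (1.65 ± 0.40) and Hmgb2 (0.80 ± 0.20). The immature NK list fell, with 1 higher and 5 lower of 9 measured (1 and 6 adjusted over the list alone, camera adjusted p = 0.000131): Tcf7 fell from 532 ± 89.3 to 165 ± 87.0 CPM (-1.64 ± 0.28), with Cd27, a costimulatory receptor of immature NK cells (-1.15 ± 0.31), and the homing receptor gene Sell (-0.67 ± 0.18), while Thy1 rose by 0.62 ± 0.19. Interferon-stimulated genes were lower as a set, with 0 higher and 1 lower of 19 measured (0 and 1 adjusted over the list alone, camera adjusted p = 0.00445, 0.0901 with an estimated correlation), Irf7 being the member that passed (-1.33 ± 0.36). The erythroid and platelet list was not lower as a set but its haemoglobin genes were, with 0 higher and 4 lower of 5 measured (0 and 5 adjusted over the list alone, camera adjusted p = 0.251, 0.603 with an estimated correlation), and in the control they came mostly from 1 library, which held 31460 per 1000000 UMIs. In all 210 of 3228 genes passed (79 higher and 131 lower), and with the run as a term 250, where the log2 difference was 1.96 for Gzmb (adjusted p = 5.28e-07) and -1.76 for Tcf7 (adjusted p = 1.29e-05). Without run 16 of B16_Tumor_CpG 27 passed, with libraries summed by run 28, and among wells of at least 1000 UMIs 69.

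B16 spleen libraries held 27883 to 57589 UMIs in control and 76335 to 332331 with CpG. Klrg1 rose with CpG from 71.9 ± 40.0 to 711 ± 159 CPM (SD, n = 4 and 4), a log2 difference of 3.32 ± 0.47 (adjusted p = 0.000137, 4 of 4). Ly6a rose by 2.37 ± 0.46, Cd244 by 2.26 ± 0.49, S100a6 by 1.30 ± 0.28 and the thioredoxin gene Txn1 by 1.23 ± 0.26, and Rabac1 fell (-1.44 ± 0.32). Capg, an actin-capping protein gene, rose with a ratio of 11.9 (counting interval 3.21 to 100). MHC class I processing genes were higher as a set. Measured members numbered 16, with 0 higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.00115). In all 10 of 3228 genes passed (9 higher and 1 lower). With median-of-ratios scaling 16 passed (9 and 7), with the run as a term 29, and with DESeq2 52. With libraries summed by run 1 passed, among wells of at least 1000 UMIs 4, and without run 17 of B16_Spleen_cntrl 0 (edgeR, 453 at an unadjusted p under 0.05). Leaving out single libraries left 3, 2, 2 and 6 genes without B16_Spleen_CpG replicates 1 to 4 and 10, 2, 1 and 8 without B16_Spleen_cntrl replicates 1 to 4.

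Without CpG, tumour and spleen of B16-bearing mice differed in maturation and proliferation genes. Klf2 was lower in B16_Tumor_cntrl at 47.3 ± 23.9 against 411 ± 120 CPM (SD, n = 6 and 4), a log2 difference of -3.07 ± 0.40 (adjusted p = 7.00e-06, 6 of 6 below the spleen mean), as were Cma1 (-4.73 ± 0.79), Ccl5 (-1.32 ± 0.18) and Gzma (-0.82 ± 0.16). The NK maturation and circulation list was lower, with 1 higher and 3 lower of 11 measured (1 and 5 adjusted over the list alone, camera adjusted p = 0.000155), Irf8 being its higher member (1.27 ± 0.29). Xcl1 was higher by 1.58 ± 0.28, Gzmb by 1.22 ± 0.34, and Thy1 by 1.04 ± 0.27. The ratio was 16.2 for Cd69 (counting interval 2.81 to 653). Interferon-stimulated genes were higher, with 3 higher and 0 lower of 19 measured (5 and 1 adjusted over the list alone, camera adjusted p = 0.000155), among them Stat1 (1.21 ± 0.30) and Zbp1 (2.17 ± 0.52), and so were the interferon-gamma-induced GTPases as a set, with 0 higher and 0 lower of 8 measured (3 and 0 adjusted over the list alone, camera adjusted p = 0.00203). Proliferation genes were lower in the tumour, with 0 higher and 7 lower of 24 measured (0 and 12 adjusted over the list alone, camera adjusted p = 1.09e-14), as in Mki67 (-2.01 ± 0.48). B cell genes were counted in the spleens, with 0 higher and 3 lower of 4 measured (0 and 3 adjusted over the list alone, camera adjusted p = 1.64e-07), Igkc averaging 2355 ± 3717 CPM there and 0 in the tumour, and antigen presenting cell genes were lower in the tumour, with 0 higher and 3 lower of 5 measured (0 and 4 adjusted over the list alone, camera adjusted p = 2.39e-07). The red cell genes Slc4a1 and Slc25a37 were lower in the tumour, with a ratio of spleen to tumour for Slc4a1 of 205 (counting interval 55.5 to 1714) and a log2 difference for Slc25a37 of -3.58 ± 0.80, and haemoglobin took 27830 ± 25200 per 1000000 UMIs in B16_Spleen_cntrl (SD, n = 4). In all 104 of 3228 genes passed (52 higher and 52 lower), with median-of-ratios scaling 113 (42 and 71), with only these groups fitted 24, and without B16_Spleen_cntrl replicate 4 62.

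**Figure D3:**
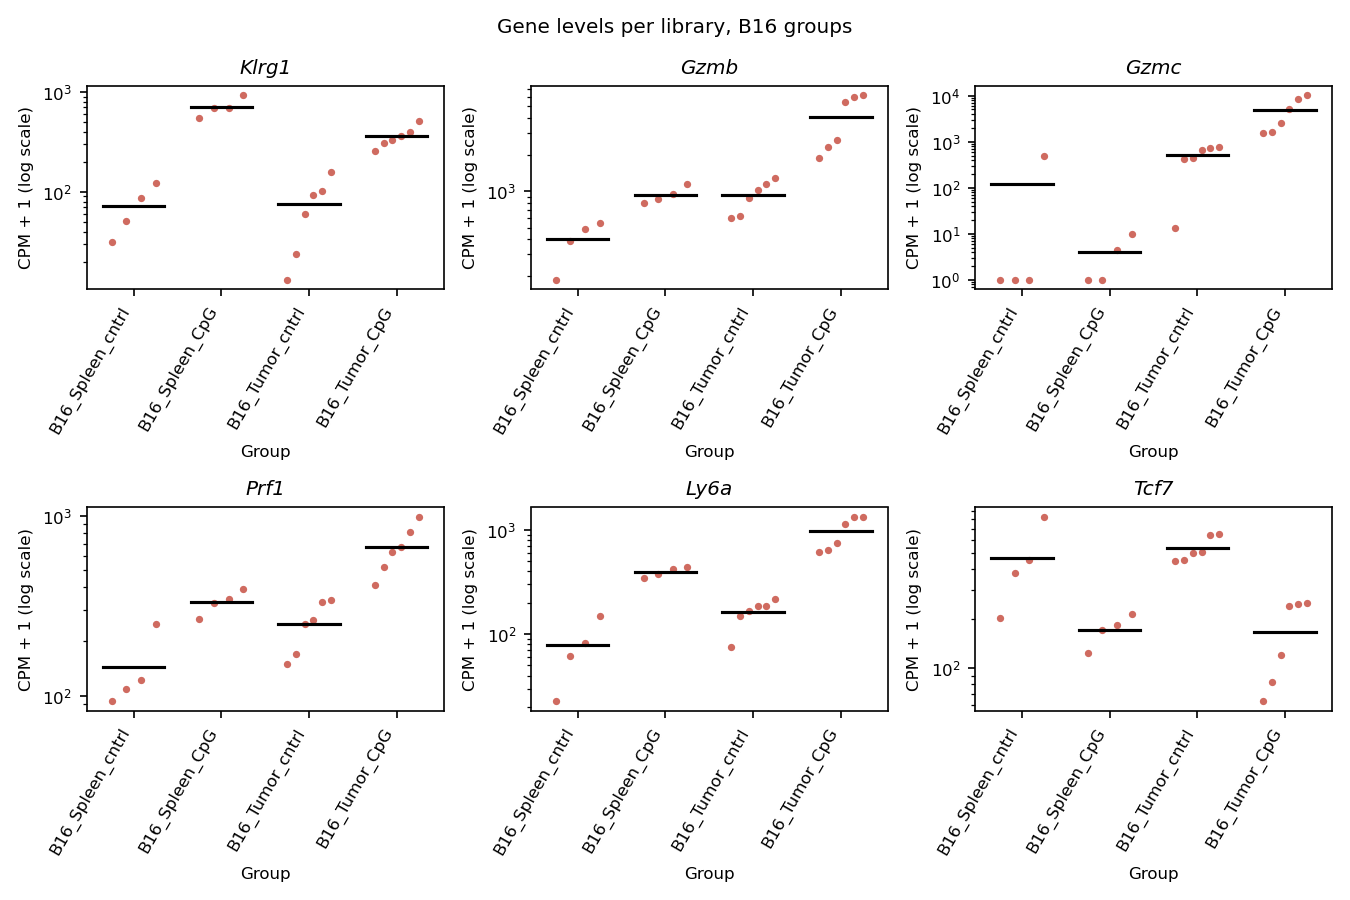
Levels of Klrg1, Gzmb, Gzmc, Prf1, Ly6a and Tcf7 (vertical axes, CPM plus 1 on a log scale) in each library (points) of the 4 B16 groups (horizontal axes), with the group mean as a line. All B16_Tumor_CpG libraries lie above the mean of B16_Tumor_cntrl for the first 5 genes and below it for Tcf7.

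Whether CpG acted differently in tumour and spleen was tested as an interaction. No single gene passed (edgeR, 0 of 3228 genes, 258 at an unadjusted p under 0.05, 4 with DESeq2, 2 with the run as a term). The glycolysis and hypoxia list differed as a set, the response being larger in the tumour. Measured members numbered 15, with 0 higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 2.17e-07). Its member Pkm2 had an interaction of 1.02 ± 0.33 (adjusted p = 0.449). Klrg1, which passed in both tissues, had an interaction of -1.12 ± 0.64 (adjusted p = 0.684), and Gzmb of 0.91 ± 0.45 (adjusted p = 0.622). Among NK-like wells, of which cluster 1 held the most in B16_Tumor_CpG, cluster 0 in B16_Tumor_cntrl and cluster 4 in the B16 spleen groups, 41 of 1252 genes passed (25 higher and 16 lower) between B16_Tumor_CpG and B16_Tumor_cntrl. Ly6a (3.09 ± 0.35), Gzma (1.25 ± 0.19), Gzmb (1.67 ± 0.30), Prf1 (1.39 ± 0.30), S100a4 (2.16 ± 0.34) and Ly6c2 (1.62 ± 0.41) rose there and Tcf7 fell (-1.45 ± 0.31). The cytotoxic effector list rose in these wells, with 3 higher and 0 lower of 11 measured (6 and 0 adjusted over the list alone, camera adjusted p = 6.14e-06), and glycolysis and hypoxia, with 3 higher and 0 lower of 10 measured (7 and 0 adjusted over the list alone, camera adjusted p = 2.43e-06). Between NK-like wells of B16_Spleen_CpG and B16_Spleen_cntrl 14 of 1252 genes passed (9 higher and 5 lower): Klrg1 (3.55 ± 0.60), Cd7 (1.67 ± 0.33) and Tmsb4x (0.74 ± 0.17) rose and Rabac1 fell (-1.75 ± 0.41). Ly6a rose there with a ratio of 36.5 (counting interval 6.39 to 1454) and Tspan13 with 21.7 (3.75 to 872). A run term gave 63 and 20 genes. Without run 16 of B16_Tumor_CpG 2 passed in the tumour wells. With libraries summed by run the numbers were 7 and 3. In the spleen wells 9, 8, 5 and 7 passed without B16_Spleen_CpG replicates 1 to 4, and 18, 7, 2 and 9 without B16_Spleen_cntrl replicates 1 to 4.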

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

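Chosen only after the result was seen were the tests of the CpG response of the ILC1-like share between tissues and of wells listed with 0 cells, while other tests here were fixed before the data were examined. Libraries were compared with Dixon's test in groups of 4 to 10, over 103 sets of values, and 10 sets held a library far from the rest. Chance alone gives about 1 in 20, and several sets share libraries.

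In SG, replicate 1 lay apart in 3 sets, with an ILC1-like share of 19.67% (6.79 to 11.93 in the others), Cxcr6 at 312.6 CPM (17.93 to 116.6) and Klrg1 at 46.75 CPM (2.775 to 12.95). Gzmc was at 1087 CPM in Lymph_node replicate 1 (0 to 79.87 in the others) and at 484 CPM in B16_Spleen_cntrl replicate 2 (0 in the others). Klf2 was at 153.5 CPM in Uterus replicate 6 (26.95 to 73.72). Genes of other cells stood out in single libraries too: Alb at 196.8 CPM in Liver replicate 5 (20.66 to 94.57), Fabp4 at 7797 CPM in VAT replicate 1 (0 to 3113) and Igkc at 7897 CPM in B16_Spleen_cntrl replicate 3 (0 to 998.6). Liver replicate 1, the only Liver library outside run 10, held 395000 UMIs in kept wells, against at most 246200 in the others. No cause of these single values was tested.

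Some gene lists responded differently to CpG in B16 tumour and spleen. The ILC1-like share changed by -0.89 percentage points in the tumour and 12.63 in the spleen, a difference of -13.51 (exact permutation p = 0.0398, 1 test, not adjusted). The 64680 relabellings assume no CpG effect in either tissue, so a difference was not tested. By marker score the changes in tumour and spleen were 4.49 and 0.69, and with wells thinned to 500 UMIs -10.21 and 0.38, without relabelling. Among gene lists, camera at the preset correlation put the response higher in the tumour for glycolysis and hypoxia (adjusted p = 2.17e-07), proliferation (0.00245), cytotoxic effectors (0.00747) and antigen presenting cell genes (0.00890), and lower for MHC class I processing (0.00975), Ly49 receptors (0.0117) and immature NK genes (0.0370). With an estimated correlation glycolysis and hypoxia (0.0142) and MHC class I processing (0.0495) passed, and the adjusted p was 0.268 for proliferation, 0.146 for cytotoxic effectors, 0.194 for antigen presenting cell genes, 0.146 for Ly49 receptors and 0.128 for immature NK genes. No single gene passed in edgeR (258 at an unadjusted p under 0.05, 4 with DESeq2).

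Wells O1, O2 and P2 are listed with 0 cells in 100 libraries, yet held a median of 431.5, 254.0 and 255.5 UMIs. The wells with a cell in the same libraries had a median of 337 UMIs. Well P1, listed as empty in 128 libraries, had a median of 4 UMIs. In 28 libraries A1, A24 and P24, listed as empty too, had 43.5, 73 and 37. At least 500 UMIs were found in 46 of the O1, 29 of the O2 and 29 of the P2 wells. These wells were left out of all comparisons. Whether they received cells was not tested.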

How the results depend on the processing

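Tests with planned settings were fixed before the data were examined. Chosen after the result was seen were the tests with a run term for tissues and PyMT, alone or in a joint fit, within runs 6 and 11, without haemoglobin and salivary genes, with libraries of at least 4 kept wells, with cluster 4 unnamed and with both sequencings of a plate counted. No paired analysis was possible because the labels do not tie libraries of different groups to shared mice. Of 3563 values of named genes under other settings, 2956 kept their direction and side of the threshold, 597 kept the direction but missed the threshold, 9 changed sign and 1 changed sign without passing either way. Of 285 numbers of genes past the threshold 139 stayed within 1.5 times the main number, and of 152 share differences 102 kept direction and side.

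Settings that moved a number of genes past the threshold by over 1.5 times follow, with the number under each. With libraries summed by run, which leaves fewer samples, it was 0 for Blood, 0 for Lymph_node, 6 for Liver, 70 for VAT, 288 for SG, 46 for Uterus, 201 for IEL, 43 for LP, 9 for PyMT_Tumor, 4 for PyMT_Tumor (NK-like), 2 for PyMT_Spleen, 28 for CpG in B16 tumour, 7 for CpG in B16 tumour (NK-like), 1 for CpG in B16 spleen, 3 for CpG in B16 spleen (NK-like), 69 for B16 tumour against spleen and 2 for the interaction (edgeR, with 898 genes for Blood and 401 for Lymph_node at an unadjusted p under 0.05). With only the groups compared, which changes both the libraries behind the spread and the genes tested (1230 in place of 10032 for Blood), it was 60 for Blood, 83 for Liver, 111 for VAT, 633 for SG, 152 for PyMT_Tumor, 88 for PyMT_Tumor (NK-like), 2 for PyMT_Spleen and 24 for B16 tumour against spleen. It does not apply to the interaction, and the cause was not tested. In NK-like wells only, which hold fewer UMIs and fewer tested genes, it was 181 for Blood, 52 for Lymph_node, 70 for Liver, 113 for VAT, 319 for SG, 235 for Uterus, 360 for IEL, 119 for LP, 32 for PyMT_Tumor, 4 for PyMT_Spleen, 41 for CpG in B16 tumour, 18 for B16 tumour against spleen and 1 for the interaction. Without the filter on low counts, where more genes were tested, it was 856 for VAT, 2148 for SG, 170 for PyMT_Tumor, 51 for PyMT_Tumor (NK-like), 115 for PyMT_Spleen, 57 for CpG in B16 spleen, 22 for CpG in B16 spleen (NK-like), 209 for B16 tumour against spleen and 12 for the interaction. Adding LPL gave 613 for LP, and counting both sequencings of a plate, which treats 1 plate as 2 samples, gave 743 for Blood.

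For the next settings the cause was not tested. Among wells of at least 1000 UMIs the number was 212 for Blood, 69 for Lymph_node, 129 for Liver, 494 for IEL, 145 for LP, 13 for PyMT_Tumor (NK-like), 1 for PyMT_Spleen, 69 for CpG in B16 tumour, 22 for CpG in B16 tumour (NK-like), 4 for CpG in B16 spleen, 1 for CpG in B16 spleen (NK-like) and 1 for the interaction. With DESeq2 it was 213 for VAT, 97 for PyMT_Tumor, 79 for PyMT_Tumor (NK-like), 70 for CpG in B16 tumour (NK-like), 52 for CpG in B16 spleen, 27 for CpG in B16 spleen (NK-like) and 4 for the interaction, and with median-of-ratios scaling 16 for CpG in B16 spleen. With the run as a term it was 6 for Blood, 3 for Liver, 0 for VAT, 52 for SG, 70 for Uterus, 40 for IEL, 139 for PyMT_Tumor, 66 for PyMT_Tumor (NK-like), 63 for CpG in B16 tumour (NK-like), 29 for CpG in B16 spleen and 2 for the interaction (edgeR, for VAT 842 at an unadjusted p under 0.05), and the log2 difference changed sign for Psmb9 in Blood (0.11), Ccl5 (0.053), Gzma (0.72) and S1pr5 (0.76) in VAT, and Eomes (0.23) and Gzma (0.48) in IEL. For PyMT_Spleen, in a joint fit with the tissues, it was 0 (edgeR, 838 at an unadjusted p under 0.05), and Gzmd changed sign (-5.834). A run term could not be fitted for Lymph_node, LP and B16 tumour against spleen, where runs and groups cannot be told apart. Within run 11 the number was 116 for Uterus, within run 6 183 for PyMT_Tumor, with libraries of 4 or more kept wells 132 for PyMT_Tumor and 21 for PyMT_Spleen, and without haemoglobin and salivary genes 2 for the interaction.

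Leaving out each run or library in turn, with fewer samples, the number ranged from 159 (without run 18 of Blood) to 531 for Blood, 19 (without run 13 of Lymph_node) to 175 for Lymph_node, 10 (without run 10 of Liver) to 263 for Liver, 278 (without run 9 of Spleen) to 434 for VAT, 419 (without run 12 of SG) to 1136 for SG, 223 (without run 11 of Uterus) to 584 for Uterus, 467 (without run 12 of IEL) to 741 for IEL, 234 (without LP replicate 1) to 358 for LP, 13 (without PyMT_Spleen replicate 1) to 62 for PyMT_Tumor, 9 (without run 14 of PyMT_Tumor) to 41 for PyMT_Tumor (NK-like), 5 (without run 9 of Spleen) to 20 for PyMT_Spleen, 27 (without run 16 of B16_Tumor_CpG) to 237 for CpG in B16 tumour, 2 (without run 16 of B16_Tumor_CpG) to 110 for CpG in B16 tumour (NK-like), 0 (without run 17 of B16_Spleen_cntrl) to 10 for CpG in B16 spleen, 0 (without run 17 of B16_Spleen_cntrl) to 28 for CpG in B16 spleen (NK-like), 51 (without run 14 of B16_Spleen_cntrl) to 121 for B16 tumour against spleen and 0 (without run 14 of B16_Spleen_cntrl) to 4 for the interaction. Where a group was left with 1 library, that library was assumed to vary like the other groups. The log2 difference ranged from -0.099 (without run 10 of Liver) to 1.315 for Klrc1 in Liver and from -0.142 (without PyMT_Spleen replicate 1) to 4.269 for Pabpn1 in PyMT_Spleen, the library left out there holding the high level. Share differences, in percentage points, ranged from 5.75 to 33.83 for Liver, 16.38 to 40.17 for VAT, -0.27 to 5.44 for SG, -4.34 to 14.97 for Uterus, 0.96 to 22.75 for PyMT_Tumor, -3.87 to 2.09 for CpG in B16 tumour, 9.76 to 15.1 for CpG in B16 spleen and 9.0 to 14.33 for B16 tumour against spleen. A group reduced to few libraries may allow no p under the threshold, so calls lost here do not show a smaller difference.

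Other ways of assigning wells moved the share differences (percentage points) as follows, and the cause was not tested. With at least 1000 UMIs per well they were -5.98 for SG and -8.82 for Uterus (changed sign, now passing), -1.85 for Lymph_node, -5.21 for CpG in B16 spleen and -2.07 for B16 tumour against spleen (changed sign, not passing), 1.96 for VAT (no longer passed), -13.05 for CpG in B16 tumour (newly passed) and -10.33 for PyMT_Tumor (other sign, neither passing). With wells thinned to 500 UMIs they were 0.38 for CpG in B16 spleen (no longer passed), 21.22 for SG, 9.51 for Uterus, 26.34 for PyMT_Tumor and -10.21 for CpG in B16 tumour (newly passed) and 0.1 for Blood (other sign, neither passing). By marker score they were 0.69 for CpG in B16 spleen (no longer passed), -1.27 for Blood, 14.36 for SG and 10.37 for PyMT_Tumor (newly passed) and 4.49 for CpG in B16 tumour (other sign, neither passing). With cluster 4 unnamed they were -14.04 for SG and -12.91 for Uterus (changed sign, now passing), 5.11 for Lymph_node, 13.07 for CpG in B16 spleen and 9.99 for B16 tumour against spleen (no longer passed) and 4.03 for Blood and -7.0 for PyMT_Tumor (other sign, neither passing), where most NK-like wells of Spleen leave the denominator. With libraries pooled by run, which leaves few samples and may allow no small p, they were 7.18 for Lymph_node, 19.28 for Liver, 63.74 for LP, 12.62 for CpG in B16 spleen and 10.69 for B16 tumour against spleen (no longer passed) and 0.1 for CpG in B16 tumour (other sign, neither passing). At this depth and number of libraries, most simulated changes at a log2 fold of 1 were missed in every comparison tried but CpG in B16 tumours, and LPL and LN were not compared on their own.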

Other observations

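Chosen only after the result was seen were the tests of carry-over between libraries sequenced together, of counting noise in Liver, and of other splits of the libraries. The other tests here were fixed before their values were seen.

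Clusters 3, 5, 6 and 9 stayed unnamed under the naming rule, although some markers of a class were raised in each. Cluster 9 (1089 wells, 3 NK markers raised) was led by Gzmc, Gzme, Gzmd, Gzmb, Capg and Ccl1. It held 25.9% of kept wells in B16_Tumor_CpG against 6.01% in B16_Tumor_cntrl, 22.5% in PyMT_Tumor against 0.74% in PyMT_Spleen, 9.77% in SG and 0.51% in Spleen, and it enters neither class of the ILC1-like share. These shares of all kept wells were not tested. LPL, with 2 libraries, had ILC1-like shares of 70.0% and 71.1%, and LN, with 1 library, 10.3% (8 of its wells ILC1-like and 70 NK-like). In LPL 22.9% of wells fell in cluster 8, led by Ccl4, Ccl3 and Ifng, against 8.58% in LP and 0.76% in Spleen. Islet hormone RNA reached 944.7 per 1000000 UMIs in a Blood library and at most 106.4 in any library of another tissue.

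Salivary RNA was found in libraries of other tissues. In the 8 libraries of IEL, LPL, LN, Uterus and VAT sequenced with SG replicates 1 and 2, the lowest level was 11.86 per 1000000 UMIs, against at most 5.38 in 16 libraries of these tissues sequenced without SG (ratio 2.204). The 6 IEL libraries sequenced with SG replicates 3 to 7 held 10.59 to 389.8. Of 3072 wells of the 8 libraries 12.2% held a salivary UMI, against 94.7% in the SG libraries of the batch and 0.033% (2 of 6144 wells) in the 16 libraries sequenced without SG. Across 384 well positions the counts followed those of the SG libraries of the batch (median rank correlation 0.252, at most 0.088 in 100 random pairings, -0.002 with SG libraries of the other batch). Carry-over at the same well position could give these values. Sorted gland cells could give the small share of wells, but the gate on NK1.1 and NCR1 should remove them. They would not follow the positions, which argues against gland cells alone in these 8 libraries, not against a part. Of 95 libraries in batches without SG, 9 also reached 11.86, up to 138 in B16_Tumor_CpG replicate 4. A biological source was not tested.

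The ILC1-like share ran from 9.86% to 80.6% over the 6 Liver libraries of run 10, and counting noise is argued against (chi-square p = 2.22e-62). Depth is argued against as well, since with wells thinned to 500 UMIs the range was 66.83 percentage points in place of 70.71. By marker score it was 28.08 with nearly the same order (rank correlation 0.943), so its size may depend on the rule that names the wells. Levels that need no such rule differed too: Liver replicates 3 and 5 had Eomes at 4.1 and 0 per 1000000 UMIs and Cxcr6 at 670.2 and 909.9, and replicate 2 had 308.2 and 63.0. The labels do not tell these libraries apart, so no biological explanation was tested.

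For the genes that changed with CpG in B16 tumours, haemoglobin and salivary RNA taking up counts is argued against, since without those genes 94.1% (193 of 205) still passed. Within NK-like wells the median change of the 151 genes measured there, in the direction called, was 0.84 times that over all wells (0.75 against 0.90 on the log2 scale, 0.78 to 0.91 over genes drawn again), 151 of 151 kept their sign (the calls include these wells), and 39 passed. NK-like clusters shifted too (cluster 0 held 12.7% of wells with CpG, 25.6% in control). So the ratio sets no limit on the make-up of the sorted cells, which stays open beside a response of NK cells.

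Other splits of the same libraries were fitted with the groups compared alone. In the comparisons with Spleen the real split called more genes than any other split, being 1 of 100 splits each time. It gave 60 for Blood (highest of the other splits 1), 113 for Lymph_node (1), 83 for Liver (2), 111 for VAT (13), 633 for SG (93), 337 for Uterus (132), 597 for IEL (2) and 316 for LP (4). The same holds for CpG in B16 tumours with 224 (39), its NK-like wells with 55 (7) and B16 tumour against spleen with 24 (5), 1 of 100 splits each, and for CpG in B16 spleens with 11 (1) and its NK-like wells with 15 (2), 1 of 35 splits each. For the interaction the real split gave 0 genes in edgeR (258 at an unadjusted p under 0.05, 4 with DESeq2) and the highest other 1. All 100 splits give at least 0 by construction, so this says nothing of chance. In the comparisons between tissues, excluding chance does not tell run from group.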
